A study of Equus caballus with 23 samples.

How the data were processed

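RNA abundance was measured in 23 synovial membrane samples from the fetlock joints of 12 horses (Equus caballus), which the labels number R001 to R012. The series describes a cross-sectional study of cadavers, and its title names osteoarthritis of the fetlock in racehorses. The labels give the horse, the limb, an age without a unit and a sex code for each sample, but no disease status, so joints with and without osteoarthritis were not compared. Per the labels, tissue was pulverized in a shaker mill, total RNA was isolated on Qiagen RNeasy columns, and Lexogen QuantSeq FWD V2 libraries, which read the 3′ ends of transcripts, were sequenced on an Illumina NextSeq.

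The submitters named FastQC 0.12.1, STAR 2.7.11b, featureCounts without a version, Subread 2.0.3 and the genome build EquCab3.0. The strand setting and the treatment of reads that map to several places are not given in the sources used here. The deposited files hold raw, unnormalised read counts per gene, 1 file per library, and checking them showed whole numbers with totals from 52935 to 13737499. Gene identifiers and coordinates were taken from the deposited files. The lines of 7 genes with very long exon lists were broken in the files, so those genes were left out. Of the 30145 genes used, 22958 had a count in at least 1 library. XIST was not used here.

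Libraries were grouped by limb into left hind (9), right hind (7), left front (3) and right front (4). For horse R005 the left hind and right front joints were held, for R007 the left hind joint alone, and for every other horse both joints of 1 pair of limbs. By the labels, the joints of a horse come from the same animal and are paired. After limb group means were removed, the correlation between the joints of a horse ranged from -0.13 to 0.52 over 11 pairs, with a median of 0.0874, and 10 of the 22 libraries were closest to the other joint of their own horse. The number after the first letter of the library name (4, 5 or 6) was read as a plate column, an interpretation that the labels do not state. All libraries carry the same flow cell label.

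Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Scores, permutation tests and plots used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The main test for each gene was the edgeR quasi-likelihood F test on TMM-normalised counts after filterByExpr, two-sided, with Benjamini-Hochberg adjusted p below 0.05. Standard errors (SE) of log2 fold changes were derived from the F statistic. Levels are library-scaled counts (CPM, as edgeR computes them) scaled by TMM, with the standard deviation (SD), except where they are called plain CPM, which are divided by the library total alone.

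Right was compared with left over all 23 libraries, unpaired, with a block for the horse as an alternative. Front was compared with hind on counts summed per horse, 3 horses against 8, without R005. Age was tested as a linear trend on counts summed per horse, in the 7 horses whose joints carry a single age label. Differences between horses were tested over the 22 libraries of the 11 horses with both joints, with the joints as replicates. The intraclass correlation (ICC) given beside a gene was computed on log2(CPM + 1).

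For the title's subjects, a CD8 score (the mean over 14 CD8 and cytotoxic T cell markers) and a TNF target score (the mean over 42 TNF and NF-κB target genes) were computed from TMM log2 CPM with a prior count of 2, centred per gene. CD86 was taken as a single gene. The 3 relations among these were tested across 12 horses (mean of the joints) and within 11 horses (right minus left joint). Pearson and Spearman coefficients were used, each with a two-sided permutation p from 100000 resamples, or from exact enumeration below 10 values. Values were adjusted by Benjamini-Hochberg over the 6 relations.

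The comparisons, tests, alternatives, 35 gene lists and rule for naming genes were fixed before the data were examined. The lists cover cell types, signalling, matrix, metabolism and limb identity. Lists with at least 5 tested members were tested with camera on limma-voom values, with an inter-gene correlation preset at 0.01 and, as an alternative, estimated from the data. For differences between horses, where no single direction exists, the number of called members was compared with 10000 random lists matched on expression. Named genes were those with the largest log2 fold changes among genes past the threshold with a mean log2 CPM of at least 1, up to 12 in each direction. For horse differences they were the 25 with the smallest p, and where nothing passed, the 3 with the smallest p in each direction. Members named as examples of a tested list were among the 4 with the smallest p, and for some lists none were named. CD8A, CD8B, CD86, TNF, TNFRSF1A, TNFRSF1B, TBX5, TBX4 and PITX1 were given where tested, except CD8B and the limb genes for age.

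Each gene test was tried on counts simulated from the real gene means, dispersions and library sizes, with 200 genes changed by known amounts. The simulated counts held no outlying library and no difference between horses in unchanged genes, so the rates hold for such data only. At a log2 change of 2 the test recovered 91.0% of changed genes for right versus left and 76.1% for front versus hind. At a log2 change of 1 it recovered 53.7% and 17.9%. For horses the change was set as an SD of log2 levels between horses, which is not comparable with a difference between 2 groups. At an SD of 2 that test recovered 100%, and at an SD of 1 it recovered 98.5%. A trend of 0.5 per unit of age was recovered in 55.2% of changed genes. False calls were 8 of 166, 7 of 136, 27 of 226 and 12 of 181 for side, position, horse and age, so the test between horses had more false calls than its nominal share of 0.05.

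A count of 0 allows up to 3 counts of the library total, which is 0.218 plain CPM in the deepest library and 56.7 plain CPM in the shallowest. Such limits cover counting error only, since reads without molecular identifiers are not independent molecules. Alternatives were size factors of the DESeq2 type in edgeR, DESeq2 itself, no filter on low counts, a block for the horse, the plate column as a covariate, one side or hind joints alone, and leaving out each horse. Alternatives added after the data had been seen left out the 3 libraries under 200000 counts, left out each horse from the list and correlation tests, removed plate column means from the scores, and displaced the age labels.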

Results

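RNA from synovial membrane, the tissue that lines the joint, was measured in 23 fetlock joints of 12 horses. The samples comprised 9 left hind, 7 right hind, 3 left front and 4 right front joints. The total gene count was between 52935 and 11337607 in left hind libraries and between 135082 and 12563413 in right hind libraries. It was between 4114858 and 11542381 in left front libraries and between 1477696 and 13737499 in right front libraries, and the median over all 23 was 6386877. R001 left hind (52935), R006 right hind (135082) and R011 left hind (166994) held fewer than 200000 counts, and the next lowest, R002 right hind, held 1187867. Between 7110 and 18275 genes had a count in a library, mitochondrial genes took 2.63% to 10.8% of counts, and the 10 most abundant genes took 9.43% to 17.6%. Age labels differed between the joints of 5 horses and sex labels between the joints of 3, so sex was not compared and age was tested in the other 7 horses.

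**Figure D1:**
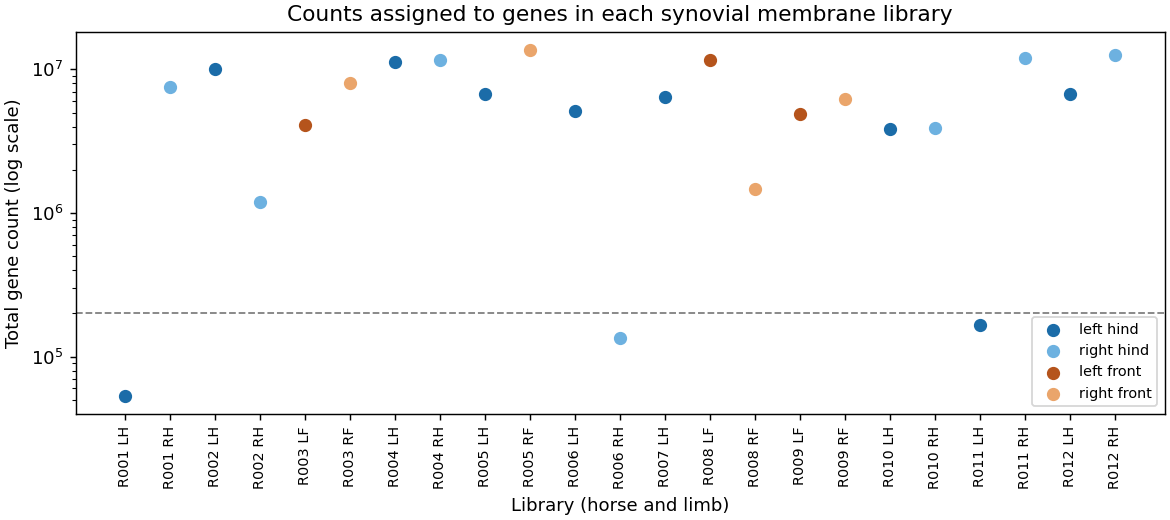
Total gene count of each of the 23 libraries on a log scale, coloured by limb, with a dashed line at 200000 counts. R001 left hind, R006 right hind and R011 left hind lie under the line, and the other 20 hold at least 1187867 counts.

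Front and hind fetlocks were compared to ask whether synovial membrane differs with limb position. PITX1, a transcription factor that specifies the hindlimb in the embryo, fell in front joints by a log2 fold change of -5.89 (SE 0.87, adjusted p = 0.0389). It averaged 0.285 ± 0.432 CPM (SD, n = 3 horses) in front and 16.3 ± 9.17 CPM (SD, n = 8 horses) in hind horses (EquCab3.0 chromosome 14, 40218266 to 40224838). Each of the 7 front libraries lay at or below 0.927 CPM and each of the 16 hind libraries at or above 6.55 CPM. SAA1, an acute phase protein, rose in front joints with a log2 fold change of 5.85 (SE 0.75, adjusted p = 0.0155), from 0.897 ± 0.566 CPM (SD, n = 8) in hind to 53.9 ± 52.4 CPM (SD, n = 3) in front horses (chromosome 7, 88539140 to 88543005). Front horse R008 had 106 CPM of SAA1, whereas R009 had 0.978 CPM, within the hind range of 0.128 to 1.90 CPM.

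The other limb identity genes did not pass the edgeR test over all genes. TBX4, the hindlimb partner of PITX1, had a log2 fold change of -3.44 (SE 0.64, adjusted p = 0.0928), with 0.349 ± 0.186 CPM (SD, n = 3) in front and 3.88 ± 2.12 CPM (SD, n = 8) in hind horses (chromosome 11, 34931593 to 34963848). TBX5, its forelimb counterpart, had 1.42 (SE 0.26, adjusted p = 0.0925), with 144 ± 59.6 CPM (SD, n = 3) in front and 53.8 ± 12.7 CPM (SD, n = 8) in hind horses (chromosome 8, 20832561 to 20898059). Both passed with DESeq2 (TBX4 adjusted p = 0.000147, TBX5 0.00330) and without a filter on low counts (0.0425 and 0.0323), and TBX5 passed without R009 (0.0357). R005, which was outside the test, gave a comparison within 1 animal. PITX1 was 19.4 CPM in its left hind and 0.382 CPM in its right front joint, TBX4 was 5.23 and 0.840 CPM, and TBX5 was 47.2 and 85.6 CPM. SAA1 differed little there, at 6.54 CPM in the left hind joint, above the range of the tested hind horses, and 8.86 CPM in the right front joint. The hindlimb list fell in front joints (5 of 6 members negative, adjusted p = 0.000849, and adjusted p = 0.133 with an estimated correlation). PITX1 and TBX4 fell when adjusted over the list alone, and 1 of these, PITX1, over all genes. Without R008 this list had adjusted p = 0.324. The forelimb list was not called (adjusted p = 0.185), and 1 of its 9 members, TBX5, rose when adjusted over the list alone.

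**Figure D2:**
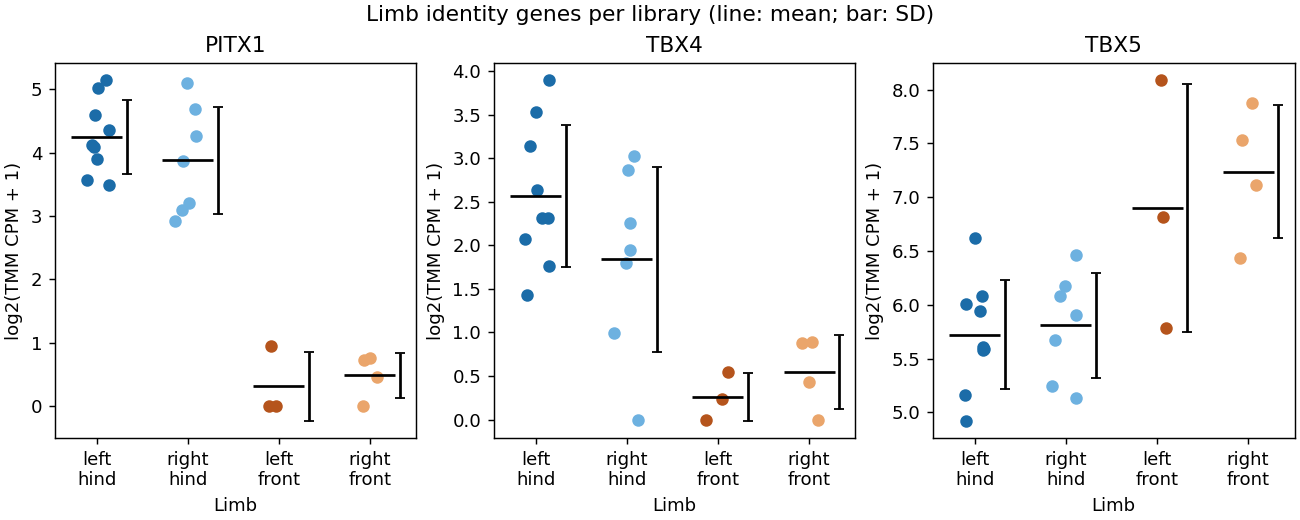
Levels of PITX1, TBX4 and TBX5 as log2(TMM CPM + 1) in each library, by limb, where the line is the mean and the bar the SD. PITX1 is at or below 0.927 CPM in all 7 front libraries and at or above 6.55 CPM in all 16 hind libraries.

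In all, edgeR called 3 of 14681 genes, 2 higher and 1 lower in front joints (568 at an unadjusted p under 0.05), and DESeq2 called 22. The remaining gene, LOC100061216, has no symbol and was named after its values were seen (chromosome 12, 23531232 to 23556333). It had a log2 fold change of 2.64 (SE 0.41, adjusted p = 0.0445), with 43.6 ± 16.3 CPM (SD, n = 3) in front and 6.92 ± 3.94 CPM (SD, n = 8) in hind horses. Except in R005, front and hind joints came from different horses, and single horses decided the count. It was 0 without R006 and 0 without R007, and it was 10, 15 and 21 without R003, R008 and R009. SAA1 had adjusted p = 0.0740 without R006 and 0.0522 without R007. PITX1 had adjusted p = 0.0531, 0.0740, 0.0908, 0.0505 and 0.0623 without R003, R006, R007, R008 and R010. LOC100061216 had adjusted p = 0.0821, 0.0714, 0.0725, 0.0793, 0.0740, 0.104, 0.130 and 0.0670 without R001, R002, R003, R004, R006, R007, R011 and R012. In right fetlocks alone SAA1 had 5.10 (adjusted p = 0.267) and PITX1 -5.37 (adjusted p = 0.261). Over the fits without 1 horse in which these calls were lost, the log2 fold change lay between -5.92 and -5.30 for PITX1, 5.72 and 5.84 for SAA1, and 2.41 and 2.72 for LOC100061216. With the horse as a block over all 23 libraries, 2 genes were called, and SAA1 was no longer among them (log2 fold change 3.49, SE 0.85, adjusted p = 0.604). With the plate column added to that fit, the 3 genes of the main test were called, SAA1 among them.

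As groups, genes of cell division and T cells were higher in the 3 front horses by the test with the preset correlation, while B cell and plasma cell markers were not called (adjusted p = 0.482). Of 100 splits of the horses into 3 and 8, the real one included, 6 gave as many called lists as the 16 of the real split (median of the others 7). Chance is therefore not excluded for the lists between positions. Of 19 proliferation genes, 18 had a positive fold change and 13 rose when adjusted over the list alone, with 0 over all genes (list adjusted p = 1.85e-19, and adjusted p = 0.0920 with an estimated correlation). Among them, TOP2A, which untangles DNA during division, had a log2 fold change of 2.47 (SE 0.42), CCNB1, a mitotic cyclin, 2.75 (SE 0.51) and MKI67, a marker of cycling cells, 1.98 (SE 0.41). The left front library of R009 was the highest of all for 15 of the 19. Front horse R009 had 66.0 CPM of TOP2A and 24.7 CPM of CCNB1, against 17.1 and 4.34 CPM in R003 and 16.8 and 3.07 CPM in R008. Without R009 the list had adjusted p = 7.31e-07. All 11 CD8 and cytotoxic T cell genes had a positive fold change, and 1, GZMA, rose when adjusted over the list alone (list adjusted p = 1.47e-07, and adjusted p = 0.182 with an estimated correlation). GZMA, a granule protease of killer cells, had a log2 fold change of 1.21 (SE 0.36), and PRF1, which forms pores in target cells, 1.44 (SE 0.50). CD8A had 0.71 (SE 0.42) and CD8B 0.98 (SE 0.52). General T cell genes were positive in 17 of 19, with CD27 at 1.52 (SE 0.66), LCK at 0.89 (SE 0.44) and 0 past the test over the list alone (list adjusted p = 1.47e-07, and adjusted p = 0.182 with an estimated correlation).

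Inflammatory genes were also higher as groups, and these calls rested on R008. Its left and right libraries had mitochondrial shares of 10.8% and 9.23%, against 10.3% and 9.89% in R004 and at most 7.02% elsewhere, and the highest shares in the 10 most abundant genes (16.1% and 17.6%, against at most 14.2%). TNF and NF-κB target genes were positive in 31 of 40, and 6 rose when adjusted over the list alone (list adjusted p = 4.09e-05, and adjusted p = 0.322 with an estimated correlation). CCL2, which attracts monocytes, had a log2 fold change of 5.26 (SE 0.95, adjusted p = 0.0925), with 222 CPM in the highest and 2.30 CPM in the lowest front horse. TNFAIP2 had 1.96 (SE 0.43). Interferon response genes were positive in 23 of 26, and 5 rose when adjusted over the list alone (list adjusted p = 1.15e-10, and adjusted p = 0.182 with an estimated correlation). RIGI, a sensor of viral RNA, had 1.70 (SE 0.39) and MX1, an antiviral GTPase, 1.06 (SE 0.31). Inflammatory macrophage genes were positive in 15 of 17, and 5 rose when adjusted over the list alone (list adjusted p = 2.15e-07, and adjusted p = 0.183 with an estimated correlation). The T cell chemokines CXCL9 and CXCL10 had 2.96 (SE 0.73) and 3.76 (SE 0.97). Without R008 the 3 lists had adjusted p = 0.350, 0.148 and 0.328. CD86 had a log2 fold change of 0.41 (SE 0.38), with 82.6 ± 43.8 CPM (SD, n = 3) in front and 62.7 ± 27.0 CPM (SD, n = 8) in hind horses. TNF itself had -0.12 (SE 0.91), and its receptors TNFRSF1A and TNFRSF1B had 0.38 (SE 0.21) and -0.02 (SE 0.36).

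Matrix genes were higher as groups too, and the calls of these lists were lost without R009, whose left front library stood apart in COL1A1 (48748 plain CPM, against at most 1793 in any other library). Fibrosis and TGF-β response genes were positive in 21 of 24, and 7 rose when adjusted over the list alone (list adjusted p = 1.33e-05, and adjusted p = 0.182 with an estimated correlation). LOXL2, which cross-links collagen, had a log2 fold change of 3.21 (SE 0.81) and COL5A2, a fibrillar collagen chain, 1.93 (SE 0.53). Cartilage markers were positive in 8 of 10, and 5 rose when adjusted over the list alone (list adjusted p = 0.000184, and adjusted p = 0.133 with an estimated correlation). ACAN, the core protein of aggrecan, had 3.59 (SE 0.73) and CILP2 4.64 (SE 0.95). Matrix degrading enzymes were positive in 15 of 17, and 2, the collagenase MMP1 at 4.34 (SE 0.86) and the stromelysin MMP3 at 2.46 (SE 0.66), rose when adjusted over the list alone (list adjusted p = 0.000411, and adjusted p = 0.0840 with an estimated correlation). MMP1 and MMP3 were highest in R008 (36.6 and 775 CPM), against 2.35 and 75.3 CPM in R009 and 2.30 and 104 CPM in R003. Tendon markers were positive in 7 of 9, with SCX at 3.87 (SE 0.81) rising over the list alone (list adjusted p = 0.0152, and adjusted p = 0.297 with an estimated correlation). Without R009 these 4 lists had adjusted p = 0.801, 0.0749, 0.0749 and 0.379, and the tendon list also lost its call without R007 (0.201), R008 (0.0937), R010 (0.0850) and R012 (0.0584).

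In total, 16 of 33 lists were called between front and hind, and 0 with an estimated correlation. The others were hypoxia and glycolysis genes, which were higher (adjusted p = 0.000206, and adjusted p = 0.182 with an estimated correlation), and mast cell markers, which were lower in 6 of 6 (adjusted p = 0.00347, and adjusted p = 0.182 with an estimated correlation). General macrophage markers (adjusted p = 0.00989, and adjusted p = 0.577 with an estimated correlation) and TNF receptor signalling components (adjusted p = 0.0121, and adjusted p = 0.182 with an estimated correlation) were higher. So was antigen presentation class II (adjusted p = 0.0406, and adjusted p = 0.265 with an estimated correlation). In these 5 lists 0 members passed the test over the list alone. Examples were HK2, a glycolytic enzyme, at a log2 fold change of 1.41 (SE 0.59), the mast cell prostaglandin synthase HPGDS at -0.79 (SE 0.32), TLR2 at 0.60 (SE 0.35), NFKB1 at 1.73 (SE 0.53) and CD74 at 0.29 (SE 0.32). The number of called lists was 8 without R008 and 9 without R009. Calls were lost without R008 for mast cell markers (0.0631), macrophage markers (0.272), TNF receptor components (0.746) and class II (0.0631), and without R009 for mast cell markers (0.0749), macrophage markers (0.0759) and class II (0.124). Those for macrophage markers were lost also without R001 (0.0703), R010 (0.0753) or R011 (0.153), and those for class II without R001 (0.0849), R002 (0.0754), R003 (0.351), R010 (0.0753) or R011 (0.0924). The sublining fibroblast list, not called, had a negative median (-0.17) and a positive mean (0.03), and its direction in the test was down.

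Right and left fetlocks were compared as the other contrast between joints that the labels give. No single gene passed the test. CD86, a costimulatory molecule of antigen presenting cells, averaged 68.7 ± 32.6 CPM (SD, n = 12) in left and 76.5 ± 43.2 CPM (SD, n = 11) in right joints, a log2 fold change of 0.21 (SE 0.29, adjusted p = 1.0). The values were -0.06 (SE 0.47) for CD8A, -0.48 (SE 0.44) for CD8B, -0.05 (SE 0.19) for TNFRSF1A and -0.08 (SE 0.28) for TNFRSF1B. For the limb genes they were 0.31 (SE 0.36) for TBX5, -0.35 (SE 0.58) for TBX4 and -0.55 (SE 0.75) for PITX1, and TNF was too low to be tested. The smallest p belonged to TNN, a tenascin of developing bone and tendon, at -3.25 (SE 0.88), C1QTNF6 at -3.17 (SE 0.89) and ARSI at -1.78 (SE 0.49), and in the other direction to SLC25A45 at 0.90 (SE 0.30), POC1B at 0.72 (SE 0.27) and SGF29 at 0.84 (SE 0.32). The left front library of R009 stood apart in the first 3, with 323 CPM of TNN, 387 CPM of C1QTNF6 and 48.0 CPM of ARSI, against at most 6.39, 21.2 and 10.6 CPM in any other library, and without R009 C1QTNF6 had -0.67 (SE 0.48) and ARSI -1.05 (SE 0.34).

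By edgeR, 0 of 12281 genes passed (131 at an unadjusted p under 0.05), and DESeq2 also called 0. With the horse as a block in the 11 pairs, 0 of 14832 genes passed (287 at an unadjusted p under 0.05). The difference between sides did not itself differ between front and hind joints for any of 14223 genes tested by edgeR (0 called, 419 at an unadjusted p under 0.05).

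As groups, 5 of 29 lists were called between sides, each lost with an estimated correlation. Resident macrophage markers were higher in right joints (12 of 15 positive, adjusted p = 0.00770, and adjusted p = 0.583 with an estimated correlation), with MRC1, a scavenging receptor, at 0.25 (SE 0.15) and F13A1 at 0.38 (SE 0.25). Lining fibroblast markers were higher (13 of 17 positive, adjusted p = 0.00770, and adjusted p = 0.583 with an estimated correlation), as were ribosomal proteins (23 of 25 positive, adjusted p = 0.00770, and adjusted p = 0.951 with an estimated correlation). Fibrosis and TGF-β response genes were lower in right joints (21 of 24 negative, adjusted p = 0.0140, and adjusted p = 0.794 with an estimated correlation). Of these, LOXL2 at -2.78 (SE 0.80), LOX at -1.12 (SE 0.37), COL5A1 at -1.60 (SE 0.56) and COL5A2 at -1.48 (SE 0.52) fell when adjusted over the list alone, and 0 over all genes. These 4 were highest in the left front library of R009, at 2462, 209, 7477 and 2206 CPM, against at most 132, 87.9, 537 and 223 CPM in any other library. Tendon markers were lower (5 of 6 negative, adjusted p = 0.0362, and adjusted p = 0.583 with an estimated correlation), with ASPN and FMOD, small proteoglycans that bind collagen, as the members with the smallest p. The number of called lists was 0 without R009, 2 without R003 and 9 without R011, and 12 with the horse as a block. Calls were also lost without R001 for ribosomal proteins (adjusted p = 0.0588) and lining fibroblasts (0.106) and without R012 for fibrosis genes (0.0861), and that for tendon markers without R002 (0.122), R004 (0.0544), R006 (0.0844), R008 (0.159) or R012 (0.166).

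The test between horses, with their joints as replicates, called 1144 of 14832 genes by edgeR (3669 at an unadjusted p under 0.05). Such a call can rest on a single library, as that of COL1A1 did, and limb position was not in the model. PDK4, a kinase that turns muscle and other tissues from glucose to fat oxidation, ranged from a mean of 20.4 CPM in R009 to 3129 CPM in R005 (ICC 0.96, adjusted p = 7.88e-10). EQMHCC1, an equine class I histocompatibility gene, ranged from 0.291 CPM in R009 to 114 CPM in R005 (ICC 0.97, adjusted p = 2.97e-10). SAA1 ranged from 0.133 CPM in R010 to 83.1 CPM in R008, and IL1RN, the antagonist of the interleukin 1 receptor, from 1.26 CPM in R001 to 253 CPM in R008. Among the 25 genes with the smallest p, R008 had the highest mean of both joints for CCL2 (140 CPM), CXCL9 (193 CPM), CXCL10 (59.8 CPM), TNFAIP2 (446 CPM), RIGI (316 CPM), PTGS2 (44.0 CPM), the early response genes NR4A1 (288 CPM), NR4A3 (142 CPM) and ATF3 (159 CPM), and also for NR4A2, PDE4B, RGS16 and MIP-2BETA. R009 had the highest mean for COL1A1 (28612 CPM, against 538 CPM in R008) and LRRC15 (41.5 CPM), both through its left front library. R005 had it for EVX2 (61.1 CPM) and AGTR1 (19.4 CPM), R002 for EGR3 (58.8 CPM), R003 for PIGT (43.4 CPM), R010 for GABRA3 (20.1 CPM) and R012 for NAPSA (16.7 CPM). These means weigh both joints of a horse alike, including the libraries under 200000 counts of R001 and R011. On counts summed per horse, NR4A2 was highest in R001 (111 CPM, against 70.1 in R008), and ATF3 and EGR3 in R011 (172 CPM, against 146 in R008, and 63.4 CPM, against 45.6 in R002). R008 then had 265 CPM of NR4A1, 104 CPM of NR4A3 and 165 CPM of PDE4B, against 256 CPM in R011 and 101 and 160 CPM in R001. COL1A1 in the right front library of R009 was 1537.4 plain CPM, within the range of the other libraries.

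**Figure D3:**
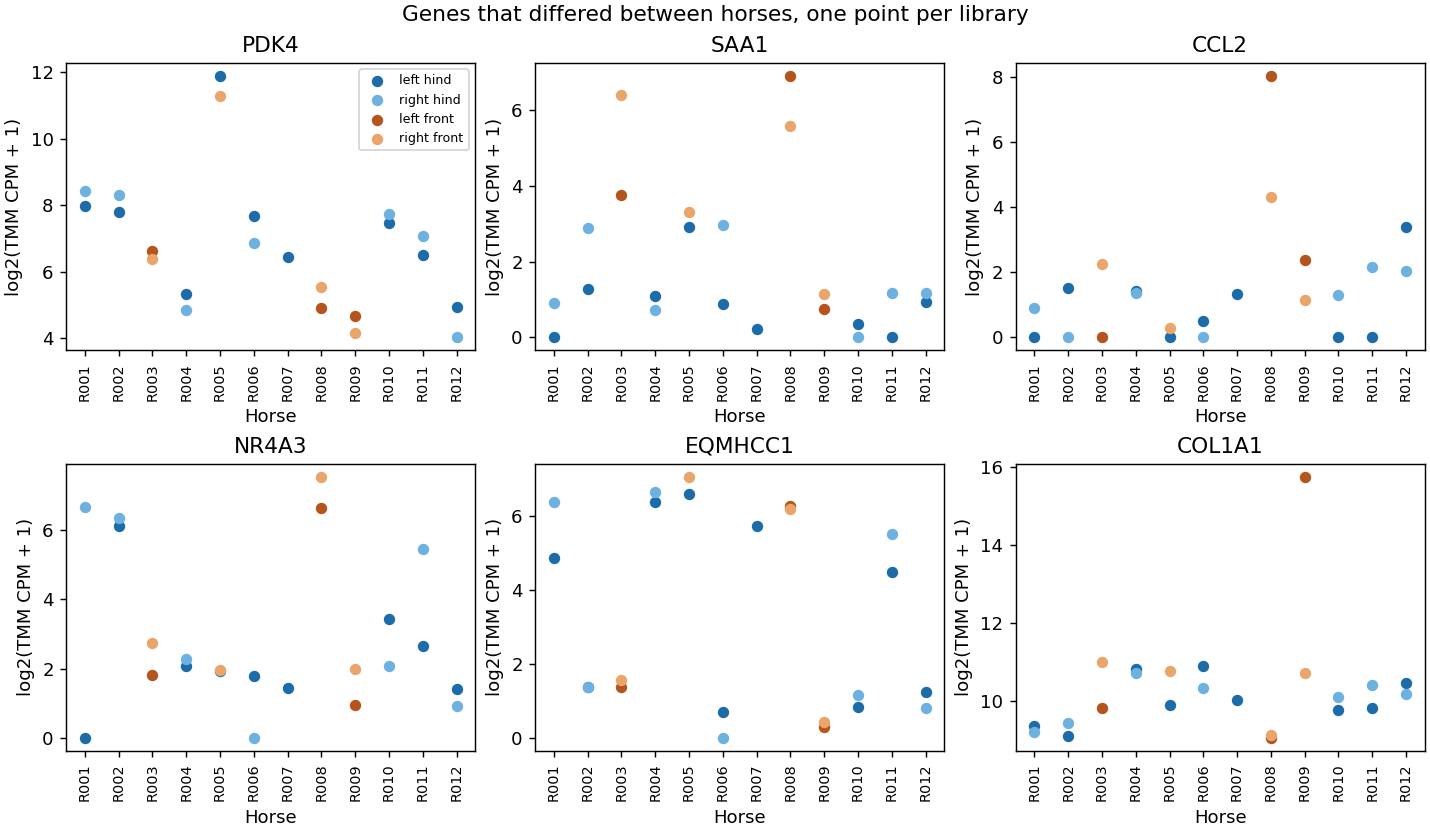
Levels of PDK4, SAA1, CCL2, NR4A3, EQMHCC1 and COL1A1 as log2(TMM CPM + 1), with 1 point per library, by horse and coloured by limb. Both joints of R005 are the highest for PDK4, and for COL1A1 the left front joint of R009 lies apart from its right front joint.

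Of the genes named by the title, CD8B differed between horses (0.873 CPM in R010 to 14.9 CPM in R009, adjusted p = 0.0472), and CD86 (39.4 CPM in R005 to 145 CPM in R008, adjusted p = 0.0695), CD8A (adjusted p = 0.172), TNFRSF1A (adjusted p = 0.575) and TNFRSF1B (adjusted p = 0.586) did not pass. The limb genes PITX1 (adjusted p = 0.00243), TBX5 (adjusted p = 0.00697) and TBX4 (adjusted p = 0.0252) did, as the horses gave different limbs. CD8B had adjusted p = 0.0674, 0.0646, 0.0547, 0.269, 0.146 and 0.0673 without R001, R004, R006, R009, R010 and R012, and 0.249 with DESeq2, 0.0628 with size factors of the DESeq2 type and 0.201 with the plate column as a covariate. CD86 passed with DESeq2 (adjusted p = 0.0346) and without a filter on low counts (0.000839), and CD8A passed without that filter (4.03e-05). TBX5 had adjusted p = 0.0522 with the plate column as a covariate, and TBX4 had 0.0732 without the 3 libraries under 200000 counts. Calls were also lost without R008 for RIGI (adjusted p = 0.183), CCL2 (0.164), RGS16 (0.317) and TBX4 (0.0708), without R009 for COL1A1 (0.0539) and TBX4 (0.0588), and without R005 for EVX2 (0.677).

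Members of several gene groups were called between horses more often than those of matched random lists. Of 23 immediate early genes, 17 were called, and 20 when adjusted over the list alone. Of 42 TNF and NF-κB targets 18 were called (26 over the list alone), of 16 inflammatory macrophage genes 8 (12), of 24 fibrosis genes 10 (16) and of 9 cartilage markers 5 (7). In these 5 lists the p from matched random lists was 1e-04, the smallest that 10000 such lists can give (adjusted p = 0.000660). Random lists do not keep the correlation between members, so these p-values are too small where the members of a list vary together. Neutrophil markers (5 of 10, adjusted p = 0.000943), proliferation (7 of 19, adjusted p = 0.000943), lining fibroblast markers (7 of 18, adjusted p = 0.00110), matrix degrading enzymes (7 of 18, adjusted p = 0.00110), bone and osteoclast markers (4 of 7, adjusted p = 0.00330) and interferon response genes (7 of 25, adjusted p = 0.0105) also exceeded them. Examples were S100A8, a neutrophil alarmin, at up to 4.13 CPM in R005, DMP1 at up to 75.7 CPM in R002, and PRG4, the joint lubricant lubricin, at 2086 CPM in R009 and 21035 CPM in R008. CD8 and cytotoxic genes (3 of 14 called, 7 over the list alone, adjusted p = 0.167), T cell genes (2 of 20, 7 over the list alone, adjusted p = 0.634) and macrophage markers (2 of 21, adjusted p = 0.669) did not exceed them. The median ICC was 0.50 for immediate early genes, but 0.11 for fibrosis genes, 0.098 for proliferation genes and 0.11 for cartilage markers. At so low an ICC the joints of a horse differed about as much as the horses did. Of the cartilage markers, 6 of 9 were highest in the left front joint of R009.

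Single horses carried several of these groups. Without R008, 10 of 39 TNF targets and 1 of 25 interferon genes were called. Without R009, 0 of 18 proliferation genes, 7 of 24 fibrosis genes, 2 of 8 cartilage markers and 3 of 17 matrix enzymes were called. Without R005, 2 of 8 neutrophil markers were called. The count of genes was 369 with the plate column as a covariate, 363 of them among the 1144, and 3626 without a filter on low counts.

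Age was tested to ask which genes follow the age label, in the 7 horses R001 to R007, with values per unit of that label. The called lists numbered 3, but 84 of 100 orders of the ages over the horses, the real one included, gave as many (median of the others 6). Chance is therefore not excluded for the 3 falls of lists given here. Macrophage markers fell with age as a group (19 of 21 negative, adjusted p = 0.0311, and adjusted p = 0.985 with an estimated correlation), with C1QC, a complement component made by tissue macrophages, at -0.45 (SE 0.13). Resident macrophage markers fell (11 of 15 negative, adjusted p = 0.0342, and adjusted p = 0.985 with an estimated correlation), with CD163, a haemoglobin scavenger receptor, at -0.44. Oxidative phosphorylation genes fell (18 of 25 negative, adjusted p = 0.0311, and adjusted p = 0.985 with an estimated correlation), of which the succinate dehydrogenase subunits SDHA at -0.39 (SE 0.09) and SDHB at -0.38 (SE 0.10) fell when adjusted over the list alone and 0 over all genes. The smallest p among single genes belonged to KIF1A, a motor protein of nerve cells, at 0.64 (SE 0.09, adjusted p = 0.351), CDH11, an adhesion molecule of synovial fibroblasts, at 0.64 (SE 0.13) and C1H1orf198 at 0.47 (SE 0.09), and to RPL35 at -0.58 (SE 0.10), RPL30 at -0.42 (SE 0.08) and MAPK13 at -0.62 (SE 0.12). CD8A had 0.26 (SE 0.16), CD86 -0.14 (SE 0.13), TNFRSF1A 0.09 (SE 0.09) and TNFRSF1B 0.13 (SE 0.11).

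By edgeR, 0 of 14703 genes passed (1170 at an unadjusted p under 0.05), DESeq2 called 50, among them KIF1A, CDH11, C1H1orf198, RPL35, RPL30 and MAPK13, and a fit with the horse as a block called 1, KIF1A (adjusted p = 0.00525). Of 33 lists 3 were called, and the number was 1 without R001, 5 without R003, 8 without R005, 6 without R006 and 0 without R007. Macrophage and resident macrophage markers were not called without R004 (adjusted p = 0.0525 and 0.0711) or R006 (0.123 and 0.378), and macrophage markers and oxidative phosphorylation were not called without R001 (0.140 each). With the age labels displaced by 1 sample, over all 12 horses, macrophage and resident macrophage markers had adjusted p = 0.858 each and oxidative phosphorylation 0.170.

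The series title relates CD8 T cells, CD86-positive macrophages and TNF signalling to osteoarthritis, and their relation to each other was tested here. Horses with more CD86 had a higher TNF target score (r = 0.718, permutation p = 0.00728, adjusted p = 0.0437; rho = 0.664, permutation p = 0.0209, adjusted p = 0.125; n = 12). R008 had the highest CD86 (7.18 log2 CPM) and the highest TNF target score (1.48), and 8 of 12 horses lay on the same side of both medians. Without the 2 horses farthest from the median of CD86, R007 and R008, r was 0.466 (permutation p = 0.174). Without R008 alone r was 0.536 (adjusted p = 0.175) and without R007 alone 0.732 (adjusted p = 0.0905), and the adjusted p was also 0.103, 0.0515, 0.0683, 0.0547, 0.0704, 0.0745 and 0.107 without R002, R004, R006, R009, R010, R011 and R012 (r between 0.681 and 0.729). The CD8 score and the TNF target score had r = 0.565 (permutation p = 0.0310, adjusted p = 0.0752) and rho = 0.601 (permutation p = 0.0441, adjusted p = 0.132), and r was 0.327 without R001 and R006 and 0.851 (adjusted p = 0.0156) without R008. The CD8 score and CD86 had r = 0.285 (permutation p = 0.367, adjusted p = 0.478) and rho = 0.0629 (permutation p = 0.852), and r was 0.232 without the 2 farthest horses. In the whole family 6 relations were tested.

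Between the joints of a horse, the right minus left difference in CD86 ran opposite to that in the TNF target score without passing the adjusted threshold (r = -0.642, permutation p = 0.0376, adjusted p = 0.0752; rho = -0.455, permutation p = 0.162; n = 11). Without R001 and R011, each with a library under 200000 counts, r was -0.0429, so this relation rested on them. For the CD8 score the values were r = 0.282 with the TNF target score (permutation p = 0.399, adjusted p = 0.478; rho = 0.209, permutation p = 0.543) and r = 0.234 with CD86 (permutation p = 0.498, adjusted p = 0.498; rho = 0.291, permutation p = 0.388). Without the 2 farthest horses they were 0.0742 and 0.269. Without the libraries under 200000 counts (n = 8) they were -0.318 and 0.721 (exact permutation p = 0.438 and 0.0490, adjusted p = 0.657 and 0.161).

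The relations were also computed without the shallow libraries and within plate columns. R001, R006 and R011, the horses with a library under 200000 counts, had TNF target scores of -0.65, -0.59 and -0.37, and without those libraries r across horses was 0.571 for CD86 and the TNF target score (permutation p = 0.0537, adjusted p = 0.161) and 0.0575 for the CD8 score and the TNF target score. Within plate columns 4, 5 and 6 (n = 6, 7 and 6), r between CD86 and the TNF target score was -0.342, -0.327 and 0.788 (exact permutation p = 0.561, 0.457 and 0.0333). Between the CD8 score and the TNF target score it was -0.0131, 0.860 and 0.124 (exact permutation p = 0.939, 0.0119 and 0.911). Plate column 5 held the 3 libraries under 200000 counts, and without them its value was 0.438 (exact permutation p = 0.467, n = 5). Between the CD8 score and CD86 it was 0.211, -0.0876 and 0.554. With all libraries, none of the relations had the same sign in all 3 plate columns. Without the libraries under 200000 counts, plate column 5 (n = 5) gave 0.402 for CD86 and the TNF target score (exact permutation p = 0.467). It gave 0.555 for the CD8 score and CD86 (exact permutation p = 0.317), whose r was then positive in all 3 plate columns. In plate columns 4 and 6 the exact permutation p of that relation was 0.719 and 0.258. Random lists matched to the CD8 list had a median r of 0.534 with the TNF target score, so its r of 0.565 lay at the 58.4th percentile. For CD86 the median r of matched single genes was 0.133, and its r lay at the 98.7th percentile. TNF itself was at or below 4.20 CPM in every library.

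**Figure D4:**
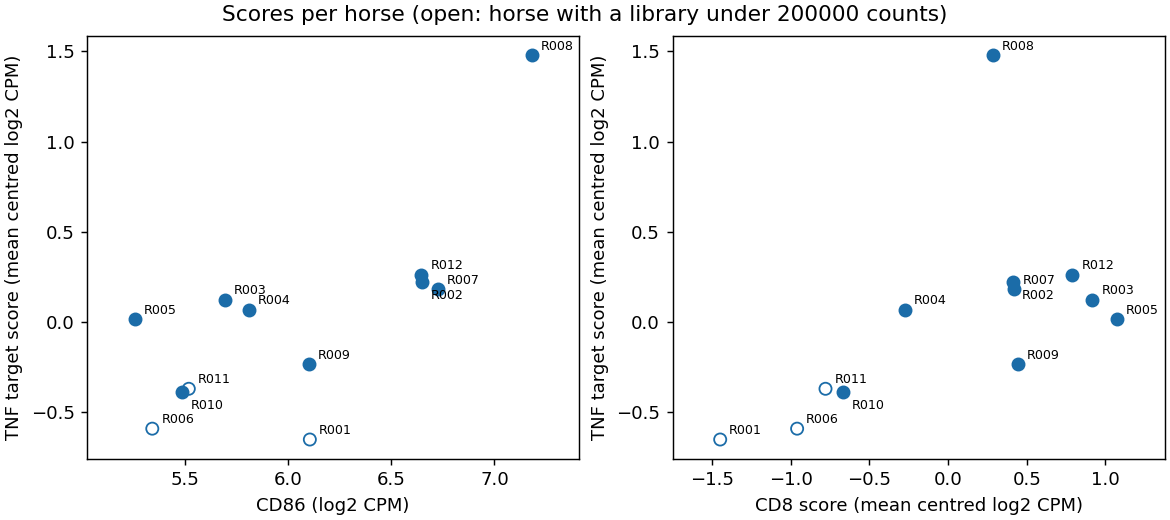
TNF target score of each horse against CD86 (left, log2 CPM) and against the CD8 score (right, mean centred log2 CPM), with open points for horses with a library under 200000 counts. R008 is highest in both CD86 (7.18) and the TNF target score (1.48), and the open points lie between -0.65 and -0.37 on the TNF target score.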

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

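Among the tests in this part, that of the X escape genes was planned, and those on LOC102150010, on the left front joint of R009 and on R005 were chosen only after the results had been seen.

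The age labels of the 2 joints of a horse differed in 5 horses and the sex labels in 3, although the labels place both joints in 1 animal. When each library from R008 left front onward was given the label of the following library, the conflicts were 0 and 0. The last library, R012 right hind, has no following library and kept its own label, so the joints of R012 became equal by construction. The planned test, on 9 X escape genes in place of XIST, decided nothing, since 0 of the 3 libraries that would then be labelled F were among the 3 highest. LOC102150010, an X-linked gene without a symbol, stood at 147 plain CPM or more in R007 left hind and both joints of R010 and at 24.0 plain CPM or less elsewhere (4 counts, in R011 left hind), which matched the displaced labels in 23 of 23 libraries and the deposited ones in 20. It was chosen for these values, so it decides nothing. Over the libraries of at least 200000 counts, 3 of 519 X-linked genes (0.578%) and 0.328% of 14313 others parted the libraries that the displaced labels call F from the rest. For the deposited labels 0 X-linked genes and 0.0769% of the others did so. The displaced labels call both joints of R010 F, whereas the deposited F libraries at this depth come from different horses. The shares are therefore not comparable, and the scan decides nothing. Sex is fixed in an animal, so the conflicts themselves show that a sex label or a horse number is wrong in each of the 3 horses. Labels displaced by 1 sample stay open as a candidate explanation.

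In the left front joint of R009, COL1A1 reached 48748 plain CPM (at most 1793 in any other library), FMOD 4520 (1124), ACAN 117 (14.5), SCX 38.4 (1.49), LRRC15 70.2 (7.40) and MKI67 85.6 (27.4), while PRG4, at 1239, was the lowest of all. The plate column or depth is argued against by COL1A1 at 1537.4 plain CPM in the right front joint of R009, of the same plate column and within the range of the other libraries. Admixed tendon or ligament stays open. TNMD was at 1.83 plain CPM (at most 0.344 elsewhere), but THBS4, at 554, lay within the range of the others. Of 7 tendon markers other than the genes above, 2 were highest in this library, at the 85.12th percentile of matched lists, which decides nothing. Cartilage markers (5 of 8 others highest, 100th percentile) and bone and osteoclast markers (3 of 7, 99.06th) stood out further, as did fibrosis (15 of 24) and proliferation genes (14 of 18), both at the 100th percentile. Against cartilage stand COL2A1, its main collagen, with 0 counts there, a value that allows up to 0.610 plain CPM, and COL9A1, COL9A3, MATN1, MATN3 and SNORC, also at 0. All of these were at or below 5.31 CPM in the other libraries too, so it is not known that cartilage would show them here, and admixed cartilage or bone stays open. No biological explanation was tested, since the labels give no disease status or injury, and growing or healing connective tissue stays open as well.

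In both joints of R005, PDK4 stood at 3419 and 2384 plain CPM (at most 361 in any other library), FKBP5 at 801 and 1182 (at most 526) and ZBTB16 at 2991 and 2154 (at most 1635). The plate column is argued against, since PDK4 reached 340 plain CPM at most in the other libraries of the columns that held R005. A list of 12 other genes that glucocorticoids induce was higher in R005 than in other horses by a mean of 0.98 (log2), at the 100th percentile of matched lists, and 6 of the 12, SESN1 and PER1 among them, were highest there, so exposure to glucocorticoids, from stress or treatment, is a candidate explanation. A list of 10 genes that respond to fasting lay at the 61.84th percentile and decided nothing. The labels give no treatment, and other differences between the animals stay open.

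A library of 1 limb group lay far from the others of its group in 18 of 147 groups of values, 6 of them in libraries under 200000 counts. Many of the genes had been named for small p-values between horses in these same libraries, so the count of 18 cannot be set against a chance rate. Values are TMM CPM, each with the nearest library of its group.

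R008 right front was highest of 4 for CD8A (27.49, next 5.50), NR4A3 (184.6, next 5.66), NR4A1 (301.8, next 17.9) and RGS16 (63.5, next 7.78), and lowest for COL1A1 (549.9, next 1683). R005 left hind was highest of 9 for SAA1 (6.535, next 1.41), PDK4 (3757, next 250.7) and EVX2 (55.87, next 5.31), and R005 right front was highest of 4 for AGTR1 (20.55, next 1.13). R012 left hind was highest of 9 for CCL2 (9.461, next 1.89), and R012 right hind was highest of 7 for NAPSA (23.42, next 1.11). R010 right hind was lowest of 7 for POC1B (1.481, next 3.99).

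In the shallowest library, R001 left hind, ARSI, CD8A and IL1RN were 0 (next 2.61, 2.45 and 3.99), where a count of 0 allows up to 56.7 plain CPM, and TNFRSF1A was 55.71 (next 126.2). R006 right hind, also under 200000 counts, had SGF29 at 0 (next 1.91), where a count of 0 allows up to 22.2 plain CPM, and was highest of 7 for KIF1A (109.1, next 30.4).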

How the results depend on the processing

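Leaving out the 3 libraries under 200000 counts, removing plate column means, leaving out horses from the list and correlation tests and displacing the age labels were alternatives chosen after the data had been seen, and the others were planned and all were run. Over the named genes with a direction, 571 of the values under alternatives kept their side of the threshold and moved by less than their error where not called, 36 moved further, 13 passed the threshold that had not and 10 no longer did. None of the called genes changed direction, and 32 values of genes that were not called changed sign. For differences between horses the corresponding calls were 539 kept, 3 gained and 19 lost. A log2 change of 1 was recovered in 17.9% of simulated genes between front and hind joints, so smaller differences between positions would mostly be missed at this number of horses.

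Between front and hind joints, 22 genes passed with DESeq2 and 20 without a filter in place of 3. With fewer joints, 12 passed in left and 0 in right fetlocks alone. Leaving out single horses gave 0 to 21 genes, with 0 without R006 or R007 and 21 without R009. For age, 50 genes passed with DESeq2, 1 without a filter and 1 with the horse as a block in place of 0, and leaving out single horses gave 0 to 0. Between horses, 3626 genes passed without a filter, which tested 22844 genes, and 369 with the plate column as a covariate in place of 1144, and leaving out single horses gave 810 to 1460. Between sides the count stayed at 0 under every alternative run.

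With an estimated correlation between genes, 0 lists passed for side, 0 for position and 0 for age in place of 5, 16 and 3. The block for the horse gave 12 lists for side, and displaced age labels over 12 horses gave 12 lists for age, with 0 of the 3 among them (0 with an estimated correlation, 5 without R008). Leaving out single horses gave 0 to 9 lists for side (0 without R009, 2 without R003, 9 without R011), 8 to 19 for position (8 without R008, 9 without R009) and 0 to 8 for age (0 without R007, 1 without R001, 5 without R003, 6 without R006, 8 without R005).

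The correlation of CD86 with the TNF target score across horses lost its adjusted p below 0.05 in 8 alternatives and without any 1 of 9 horses. It was 0.701 with plain library sizes and 0.704 with the median over list members (adjusted p = 0.0601 and 0.0559 by permutation). It was 0.466 without the 2 farthest horses, 0.332 in left and 0.258 in right joints alone, 0.571 without the shallow libraries, 0.278 in hind horses without them and 0.528 with plate column means removed. Hind horses alone gave 0.961 for the CD8 score with the TNF target score and 0.761 for the CD8 score with CD86, both past the threshold, and without the shallow libraries these were 0.154 and 0.836, neither past it. Leaving out single horses gave 0.464 to 0.851 for the CD8 score with the TNF target score, 0.536 to 0.786 for CD86 with the TNF target score and 0.177 to 0.529 for the CD8 score with CD86, and within horses -0.0229 to 0.415, -0.722 to -0.476 and 0.141 to 0.488. Left joints alone gave -0.0439 for the CD8 score with CD86, and the CD8 score with the TNF target score within horses was -0.318 without the shallow libraries. Apart from SAA1 between positions, KIF1A and the count for age and the count of lists for side, the block for the horse changed no call. The causes of these changes were not tested, except that fewer joints, horses or genes entered where so stated.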

Other observations

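The tests in this part on splits of lists were chosen after the results had been seen, and those on splits of genes were planned.

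Transcripts of synovial lining and of macrophages were present in every library. PRG4, the lubricant made by lining fibroblasts, lay between 1412 and 22767 CPM in the 23 libraries, FN1 between 6030 and 30755 CPM and CLU between 8963 and 33260 CPM. Macrophage genes were present in every library, with C1QC from 134 to 1828 CPM and MARCO, a scavenger receptor, from 13.5 to 361 CPM. Among tendon markers, FMOD, THBS4 and OGN lay between 223 and 5150, 120 and 787, and 147 and 598 CPM, whereas TNMD, SCX, MKX and KERA were at most 0.370, 1.70, 3.28 and 4.61 CPM outside the left front library of R009. ADIPOQ of fat cells was at or below 19.02 CPM, ACTA1 of skeletal muscle at or below 14.7 CPM, the B cell gene MS4A1 at or below 1.97 CPM and HBA of red cells at or below 0.495 CPM.

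Some genes were present in both joints of some horses and nearly absent from both joints of others. EQMHCC1, a class I histocompatibility gene (EquCab3.0 chromosome 20, 32013583 to 32017146), lay at or above 21.2 CPM in every library of R001, R004, R005, R007, R008 and R011 and at or below 1.98 CPM in every library of R002, R003, R006, R009, R010 and R012. PIGT, part of the complex that attaches proteins to lipid anchors (chromosome 22, 35369481 to 35378781), was 0 CPM in both joints of R002 and at most 1.02 CPM in R004, R005, R007 and R009, whereas both joints of R003, R008, R010 and R012 had at least 14.1 CPM. HBEGF, a growth factor of lining cells, ranged between horse means of 36.2 CPM in R012 and 965 CPM in R001, whose mean includes a library under 200000 counts. FKBP5 and ZBTB16 ranged from 43.6 to 1060 CPM and from 146 to 2774 CPM, both lowest in R009 and highest in R005.

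The plate column was itself tested. Between the 3 plate columns, 169 of 12992 genes passed by edgeR (2439 at an unadjusted p under 0.05). With the horse in the model, 0 of 15955 passed (431 at an unadjusted p under 0.05, and DESeq2 was not run).

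With the age labels displaced by 1 sample and all 12 horses, 0 of 14779 genes passed by edgeR (624 at an unadjusted p under 0.05) and 0 by DESeq2 (728). IL1RN had 0.94 (SE 0.15, adjusted p = 0.180) and CCL2 had 1.17 (SE 0.21, adjusted p = 0.331) per unit of age. TNF target and interferon lists rose with the displaced age (adjusted p = 7.83e-09 each), and R008 carried the highest displaced age label, 7. Neither was called with an estimated correlation (adjusted p = 0.411 each) or without R008 (0.981 and 0.836).

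Other splits of the same samples were fitted to see whether chance can be excluded, 100 in each case with the real one included. For the 1144 genes between horses, 1 of 100 pairings of libraries, the real one, gave as many, below the limit fixed beforehand. The highest other gave 643 and the median of the others was 15, so a random pairing of libraries is argued against. Except in R005, the joints of a horse also share the limb position, which random pairings break. The pairings therefore do not tell the horse from its limb position. For the 3 genes between front and hind joints, 3 of 100 splits of the horses gave as many, below the limit fixed beforehand. The highest other split, with R001, R008 and R011 set apart, gave 22, so the number of genes alone does not exclude chance. That split points to a structure of the samples, and what it is was not tested. Nor was chance excluded for the 16 lists between front and hind (6 of 100, highest other 17, with R007, R008 and R009 set apart). The same holds for the 5 lists between sides (47 of 100, highest other 13) and the 3 lists for age (84 of 100, highest other 13). For the genes between sides and for age the splits decided nothing, since every split gives at least the real count of 0 (100 of 100 each, highest others 0 and 12).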
